A study of Arabidopsis thaliana with 36 samples.

How the data were processed

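RNA was taken from pools of 3 to 4 plants, and Illumina TruSeq libraries were made from it, per the labels' protocols. Whether a library kept strand is not given in the sources used here. Reads were aligned with TopHat2 to TAIR10 and edgeR was used, per the submitters' processing notes, which give no versions. The program that counted reads, the annotation release and any filter are not given in the sources used here. The deposited table holds raw counts of reads per gene for 28775 genes, whole numbers made by the authors with no normalization, per the file headers and the values. Of its 72 columns, 36 match samples of this study and 36 do not; the latter were used in no step. Columns were assigned to group, tissue and biological replicate by comparing their names with the sample titles. An S in a name was read as leaf, being the tissue letter other than R for root. The columns not used carry a T, a letter that no title has, and what it stands for is not given. Column names carry run numbers that the labels do not explain and that could not be matched to technical replicate numbers. All opt3-2 replicates have runs 1 to 3. Columbia-0 root replicates 1 and 2 and leaf replicate 3 have runs 5 to 7, and Columbia-0 root replicate 3 and leaf replicates 1 and 2 have runs 2 to 4. No full set of 3 run numbers is shared by the genotypes, although numbers 2 and 3 occur in both. What a number stands for is not given, so an effect of the run set cannot be told apart from genotype.

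The labels give the medium as replete, and a treatment text attached to the samples speaks of 20 µM CdCl2 for 72 h. Which holds was not settled, and both genotypes carry the same texts. The labels call the replicates biological without saying whether they came from separate cultures, so p-values measure the spread between these samples. Chi-square per degree of freedom was 1.02 to 1.07 between the 3 runs of a replicate and 7.57 to 48.2 between biological replicates. The runs thus differed by little more than sampling noise, and they were summed to 12 biological replicates, 3 per group.

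Depth per summed replicate was 23981444 to 37685493 counted reads, and opt3-2 leaves were the deepest group. Reads carry no molecular identifiers here, so floors cover counting error only, and only that of the group with 0 reads. Where a group had 0 reads, the fold is a lower bound against a floor of 3 reads over the group. It takes the mean of the other group as measured, so it is no safe bound where that group had few reads. Gene identifiers were looked up in the RefSeq annotation of TAIR10.1, which gave symbols and coordinates, and 28009 matched while 766 did not. That annotation may differ from the one used for counting.

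The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on summed counts with TMM factors and the filterByExpr filter, which kept 21692 genes. A single model with a mean for each of the 4 groups had 8 residual degrees of freedom, and the common biological coefficient of variation was 0.137. Contrasts were opt3-2 against Columbia-0 in roots and in leaves, the leaf effect minus the root effect, and leaf against root in Columbia-0. P-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. Calls in both tissues were compared with the number given by independent lists and by Fisher's exact test. These designs, the gene lists, the naming rule and most alternative settings were fixed before the data were examined.

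In all, 19 lists of 209 genes were fixed: root iron uptake, iron deficiency regulators, iron storage and excess, iron trafficking, copper deficiency, copper proteins, zinc deficiency, sulfate assimilation, metal chelation, photosynthesis, oxidative stress, salicylate defence, jasmonate response, flavonoid synthesis, circadian clock, heat shock, root hair markers, endodermis markers and phloem markers. Lists with 5 or more tested members, 18 of them, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided), with Benjamini-Hochberg adjustment over the lists. Camera called 7 lists in roots, 5 in leaves and 5 for the difference between tissues. With an estimated correlation, 4, 0 and 0 were called (6, 3 and 2 at an unadjusted p under 0.05). Fry, which asks whether a list's genes move on balance one way, called 10, 6 and 8. List members with too few reads to test were FER1, VTL4, VIT1, ZIP12, MTP2, BGLU28, MT1A, MT2B, APX2, F3H and HSP17.6II.

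Genes named for roots and for leaves were OPT3, the 8 highest and 8 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1 and no overlap of replicates, and up to 4 called members of each list. Where fewer than 2 members were called, the 2 most abundant were named. For the difference between tissues, the 6 lowest adjusted p among genes called in opposite directions and the list members called so were named. For the tissue comparison, the 2 called photosynthesis and 2 called root hair genes with the largest absolute change were named. LHCB1.1 to LHCB1.3, GSTF6 and GSTF7, the PDF1.2 family, IMA1 and IMA2, and VTL1 and VTL2 are similar in sequence, and counts of these are uncertain where reads were shared. Antisense and overlapping genes cannot be separated without strand.

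Alternatives were other scaling factors (RLE, upper quartile), other filters, DESeq2 1.42.0, limma voom on summed counts and on all 36 libraries with the replicate as a block (consensus correlation 0.524), single runs, a fit per tissue, stricter thresholds, the replicate number as a block and each replicate left out in turn. Voom on 36 libraries counts runs as samples with 1 correlation for all genes, although runs of a replicate differed by little more than sampling noise. It adds no biological replicates, and its p-values can be too small. A fit with the run set of Columbia-0 as a covariate was chosen after seeing the data. Its covariate parts the run sets within Columbia-0 and has a single value in opt3-2, so it does not correct the genotype comparison for run set. Replicates of equal number were checked for pairing by the correlation of their deviations from group means. In roots these were 0.466, 0.157 and 0.460, each above the bound of 0.1, so root numbers were taken to pair the samples. The main fit, fixed beforehand, does not use this pairing, and the fit with the replicate number as a block does. Values, SE and p-values given for roots are thus unpaired unless the block is named. Columbia-0 replicate 1 and opt3-2 replicate 2 reached 0.182, so the pairing of opt3-2 replicate 2 is uncertain. The pairing comes from these values and not from the labels.

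The pipeline was tested on simulated counts with 200 genes changed. These were drawn only from genes above a minimum mean read count, so the shares recovered do not hold for genes with few reads. Far fewer genes were changed than were called in the data. The simulation thus does not show the share of false calls, or how scaling behaves, at that scale. For roots, edgeR recovered 46.3% of 1.5-fold, 89.6% of 2-fold and 98.5% of 4-fold changes, and 4.76% of calls were false (21596 genes). For leaves it recovered 50.7%, 85.1% and 93.9%, with 2.47% false calls (21598 genes). False calls were 8.29% and 6.02% with voom and 17.6% and 12.4% with DESeq2. A list shifted 1.5-fold was found by all 3 list tests, and 0 of the 17 other lists were called. Simulated genes varied independently of each other, so this does not show how the list tests behave where genes move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.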

Results

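Transcript levels were measured by RNA sequencing in roots and leaves of Arabidopsis thaliana, in the wild type Columbia-0 and in the mutant line opt3-2. OPT3, an oligopeptide transporter of phloem companion cells, is known for moving iron in the phloem, and opt3-2 is a viable insertion allele of it. Plants grew for 11 days on plates and 22 days in hydroponic culture, under 16 h of light and 8 h of dark, and 3 to 4 plants went into an RNA sample. The labels call the medium replete, although a treatment text shared by the samples mentions 20 µM CdCl2 for 72 h. The 4 groups each held 3 biological replicates, and each replicate was sequenced in 3 runs. The runs of a replicate were summed, so n = 3 in every group. Summed depth was 25828387 to 30909804 counted reads in Columbia-0 roots, 27451463 to 31065807 in opt3-2 roots, 23981444 to 30816450 in Columbia-0 leaves and 36705595 to 37685493 in opt3-2 leaves. Replicates of 1 group correlated at r = 0.978 to 0.995 across genes, which are not independent replicates. The 2 genotypes correlated at 0.962 to 0.977 in roots and 0.971 to 0.982 in leaves, and the 2 tissues at 0.551 to 0.598. Below, levels are CPM (reads per 1e+06 counted reads, scaled with TMM factors) as mean ± SD of 3 replicates, changes are log2 fold changes of opt3-2 over Columbia-0 ± SE, and adjusted p-values come from edgeR's quasi-likelihood test. The SE was worked back from that test, as the absolute log2 fold change divided by the square root of F. It is approximate, above all for genes with few reads.

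OPT3 (AT4G16370), the gene altered in the mutant, lies on chromosome 4 from 9247302 to 9250343 in TAIR10.1 and is protein-coding. In leaves its transcript fell from 102 ± 23.8 CPM in Columbia-0 to 19.4 ± 1.40 CPM in opt3-2, a log2 fold change of -2.40 ± 0.16 (adjusted p = 2.66e-06). All 3 opt3-2 leaf replicates were below all 3 of Columbia-0. In roots it was less abundant, 7.51 ± 0.798 CPM in Columbia-0 and 5.64 ± 0.774 CPM in opt3-2, and the difference of -0.41 ± 0.17 did not pass the test (adjusted p = 0.125). It passed in 1 alternative, a fit with the run-number set of Columbia-0 as a covariate (-0.47, adjusted p = 0.0494), and adjusted p ran from 0.0494 to 0.476 over all alternatives. The leaf effect minus the root effect was -1.99 ± 0.23 on the log2 scale (adjusted p = 1.71e-04). SUC2, a sucrose transporter of the phloem companion cells in which OPT3 acts, fell by 0.66 on the log2 scale in opt3-2 leaves and rose by 0.47 in roots.

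**Figure D1:**
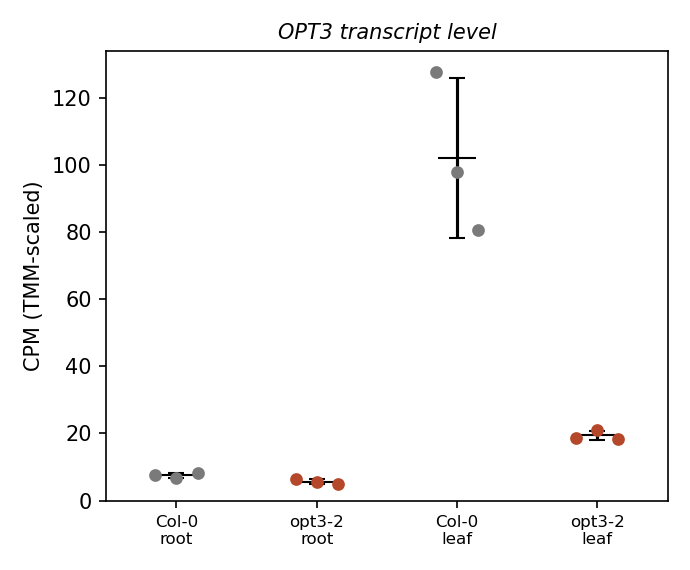
OPT3 transcript level in CPM on a linear axis for the 4 groups. Points are the 3 biological replicates, the horizontal line is their mean and the bar their SD: Columbia-0 leaves average 102 CPM and opt3-2 leaves 19.4 CPM, while root means are 7.51 and 5.64 CPM.

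Genes of the root iron uptake list were higher in opt3-2 roots. CYP82C4 (AT4G31940), a cytochrome P450 of coumarin synthesis, rose from 0.879 ± 0.534 to 1079 ± 368 CPM, a log2 fold change of 10.24 ± 0.39 (adjusted p = 2.57e-08). S8H (AT3G12900), the scopoletin 8-hydroxylase that makes fraxetin, rose from 4.26 ± 3.01 to 1582 ± 351 CPM (8.52 ± 0.51), and NAS2 (AT5G56080), a nicotianamine synthase, from 0.991 ± 0.298 to 276 ± 76.7 CPM (8.11 ± 0.26). The list of root iron uptake genes moved as a group: 19 of the 20 tested members rose and 0 fell, 20 and 0 adjusted over the list alone, with a median log2 fold change of 4.38 (camera adjusted p = 4.54e-34, and adjusted p = 0.00900 with an estimated correlation). Among its other members, CYP71B5 rose by 7.51 ± 0.23. The iron transporter IRT1 (52.3 ± 14.0 to 2433 ± 461 CPM, 5.54 ± 0.27) and the ferric reductase FRO2 (57.3 ± 13.6 to 3296 ± 852 CPM, 5.85 ± 0.24) rose as well; these 2 were singled out after their values were seen. The member that did not pass was AHA2, a plasma membrane proton pump (0.28 ± 0.13, adjusted p = 0.169). Of the iron deficiency regulators, 16 of the 17 tested members rose and 0 fell, 16 and 0 adjusted over the list alone, with a median of 2.07 (camera adjusted p = 6.78e-18, and adjusted p = 0.0115 with an estimated correlation). The transcription factors BHLH100 (6.99 ± 0.42) and BHLH38 (4.32 ± 0.38) rose, as did the peptide genes IMA2 (4.91 ± 0.74) and IMA1 (4.75 ± 0.70), which stayed at 1.58 and 1.15 CPM in opt3-2 roots. Without Columbia-0 replicate 2 the value of S8H was 9.18, and without replicate 1 that of IMA1 was 5.95.

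Across all 21692 genes tested, 3377 differed between opt3-2 and Columbia-0 roots at an adjusted p under 0.05, 1797 higher and 1580 lower. The majority turned with other settings, to 1595 higher and 1861 lower with upper-quartile factors and 1899 and 1945 with limma voom. Of the 3377, 588 were at least 2-fold higher and 233 at least 2-fold lower. The count was 2237 without Columbia-0 root replicate 1 and 2074 without Columbia-0 root replicate 2. With the replicate number as a block, which uses the pairing of root replicates, 3563 were called, and 2940 of these were among the 3377. The 8 largest increases chosen by the naming rule also held VTL3, with 0 reads in Columbia-0 roots and 787 in opt3-2 roots (at least 269-fold higher, against a floor of 3 reads over the group). The others were ZIP8 (8.07 ± 0.36), AT1G73120 (7.99 ± 0.19), AT5G55620 (7.83 ± 0.37) and AT1G52120 (7.69 ± 0.33). Among the 8 largest decreases, AT3G01345 (-5.84 ± 1.15) stood at 13.2, 0.348 and 16.6 CPM in the 3 Columbia-0 replicates and 0.173 CPM on average in opt3-2; limma voom did not call it (adjusted p from 1.55e-06 to 0.280 over its alternatives).

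VTL5, FRD3 and other genes of iron storage and trafficking were called in opt3-2 roots, in both directions. VTL5 (AT3G25190), which encodes a vacuolar iron transporter-like protein, rose from 25.1 ± 3.60 to 787 ± 35.5 CPM (4.97 ± 0.16, adjusted p = 7.29e-09), and its relatives VTL1 (3.10 ± 0.11) and VTL2 (2.99 ± 0.12) rose too. FRD3 (AT3G08040), a citrate exporter needed for iron movement in the xylem, rose from 5.21 ± 0.801 to 168 ± 23.2 CPM (5.01 ± 0.21, adjusted p = 4.89e-08). In the list of iron storage and excess genes, 5 of the 10 tested members rose and 1 fell, 7 and 1 adjusted over the list alone (camera adjusted p = 4.78e-07, and adjusted p = 0.00900 with an estimated correlation). The members that rose were VTL1, VTL2, VTL3, VTL5 and the ferritin gene FER3 (0.49 ± 0.08), and the one that fell was YSL3 (-0.83 ± 0.12), a metal-nicotianamine transporter; FER3 and YSL3 were named here after their values were seen. FER1, another ferritin gene, had too few reads to be tested. Iron trafficking genes went both ways: 4 of the 13 tested members rose and 3 fell, 4 and 3 adjusted over the list alone, with a median of -0.05 but a mean of 0.47 (camera adjusted p = 0.319, but adjusted p = 2.76e-05 by fry, which called the list higher). FPN3 (1.60 ± 0.11) and NRAMP3 (1.60 ± 0.09), organelle iron transporters, rose, and the metal-nicotianamine transporter gene YSL2 fell (-1.49 ± 0.21). The others called were NRAMP4 (0.50 ± 0.09), YSL6 (-0.37 ± 0.07) and FPN1 (-0.48 ± 0.13), named after their values were seen.

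Copper genes changed in opposite directions in opt3-2 roots. FRO5 (AT5G23990), a copper-regulated metal reductase, fell from 641 ± 38.5 to 25.6 ± 5.56 CPM (-4.65 ± 0.24, adjusted p = 1.97e-07), and CITF1 (AT1G71200), a transcription factor of copper uptake, from 8.63 ± 0.308 to 0.159 ± 0.0287 CPM (-5.72 ± 0.27). FSD1 (AT4G25100), the iron superoxide dismutase that is made when copper is short, fell from 373 ± 3.12 to 76.1 ± 39.0 CPM (-2.29 ± 0.27), and ZIP2 fell by 2.84 on the log2 scale. Of the copper deficiency list, 0 of the 10 tested members rose and 6 fell, 0 and 8 adjusted over the list alone (median -1.49, camera adjusted p = 2.62e-08, and adjusted p = 0.00612 with an estimated correlation). YSL2 is counted in this list and in the trafficking list. Of the copper proteins, 3 of the 10 tested members rose and 0 fell, 3 and 0 adjusted over the list alone (camera adjusted p = 0.00463, but adjusted p = 0.115 with an estimated correlation). The 3 that rose were the copper/zinc superoxide dismutases CSD1 (63.2 ± 2.52 to 372 ± 32.5 CPM, 2.56 ± 0.08) and CSD2 (1.29 ± 0.05) and their copper chaperone CCS (1.34 ± 0.06). In the zinc deficiency list, 2 of the 8 tested members rose and 1 fell, 2 and 1 adjusted over the list alone (camera adjusted p = 0.227, but adjusted p = 7.28e-04 by fry, higher). The zinc transporter genes ZIP9 (3.16 ± 0.17) and ZIP3 (1.02 ± 0.21) rose and HMA2, a zinc-exporting ATPase, fell (-1.01 ± 0.10). A fit per tissue did not call ZIP3 (adjusted p = 0.0538, with adjusted p from 1.55e-07 to 0.0538 over its alternatives).

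**Figure D2:**
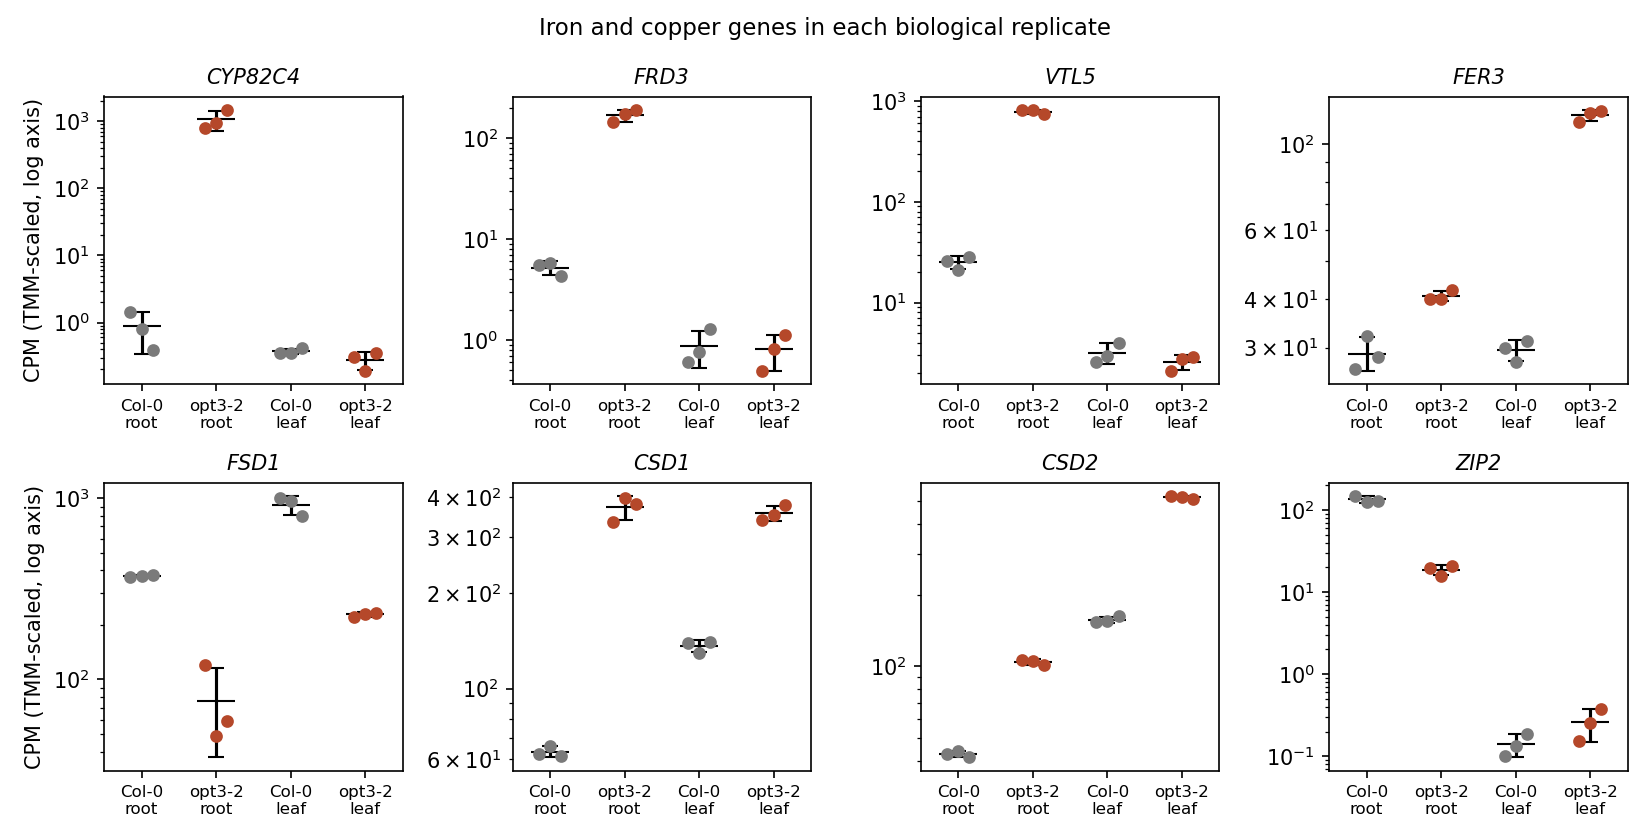
Levels of 8 iron and copper genes in CPM on log axes, with the range of each axis set per gene. Points are the 3 biological replicates of each group, horizontal lines their means and bars their SD: CYP82C4, FRD3 and VTL5 are higher in opt3-2 roots, FER3 is highest in opt3-2 leaves (118 CPM), FSD1 is lower and CSD1 and CSD2 are higher in opt3-2 in both tissues, and ZIP2 is lower in opt3-2 roots.

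Stress, defence, sulfate and chelation lists were compared in roots too. Of the oxidative stress genes, 6 of the 15 tested members rose and 0 fell, 6 and 0 adjusted over the list alone (camera adjusted p = 8.49e-05, but adjusted p = 0.115 with an estimated correlation). The glutathione transferase genes GSTU25 (3.20 ± 0.22) and GSTU24 (2.67 ± 0.19) and the ascorbate peroxidase gene APX1 (0.75 ± 0.10) rose. GSTF6 (0.84 ± 0.22), which shares sequence with GSTF7, lost its call without Columbia-0 replicate 1 or 3 or opt3-2 replicate 2 or 3 (adjusted p from 0.0561 to 0.0898). In the salicylate defence list, 2 of the 10 tested members rose and 0 fell, 2 and 0 adjusted over the list alone (camera adjusted p = 0.0291, but adjusted p = 0.416 with an estimated correlation and 0.0599 by fry), and the list's call was lost without Columbia-0 replicate 1 or opt3-2 replicate 3 (adjusted p from 0.0624 to 0.212). ALD1, an enzyme of pipecolate synthesis, rose (3.22 ± 0.48); the transcription factor gene WRKY70 (2.06 ± 0.51) lost its call without Columbia-0 replicate 1 or 2 (adjusted p from 0.0672 to 0.0818), and its value was 2.79 without Columbia-0 replicate 3 and 1.28 without opt3-2 replicate 3. In the sulfate assimilation list, 0 of the 9 tested members rose and 3 fell, 0 and 3 adjusted over the list alone (camera adjusted p = 0.0678, and 0.0330 with the replicate number as a block, where the list is called lower). The sulfate transporter genes SULTR1;1 (-1.40 ± 0.23) and SULTR1;2 (-0.86 ± 0.11) fell; APR2 (-0.58 ± 0.16) lost its call without Columbia-0 replicate 1 or 2 or opt3-2 replicate 3 (adjusted p from 0.0637 to 0.119). In the metal chelation list, 1 of the 9 tested members rose and 0 fell, 2 and 0 adjusted over the list alone (camera adjusted p = 0.284, but adjusted p = 0.0191 by fry, higher). The metallothionein gene MT2A rose (1.05 ± 0.13), and MT1C (-0.21 ± 0.08) and GSH1 (0.00 ± 0.07) did not pass.

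Of the clock, jasmonate, flavonoid and heat shock lists, edgeR called members in roots in the clock list alone. In the circadian clock list, 3 of the 10 tested members rose and 0 fell, 3 and 0 adjusted over the list alone (camera adjusted p = 0.0552, and 0.0330 with the replicate block). It was also called by fry (adjusted p = 0.0306), with a fit per tissue (0.0405) and with the run-set covariate (0.0387), and without Columbia-0 replicate 1 or opt3-2 replicate 1 (adjusted p from 0.0154 to 0.0167), and adjusted p ran from 0.0154 to 0.416 over its alternatives. PRR5 (0.56 ± 0.12) and PRR9 (0.55 ± 0.08) rose, and ELF4 (0.76 ± 0.22) lost its call without Columbia-0 replicate 1, 2 or 3 or opt3-2 replicate 2 or 3 (adjusted p from 0.0631 to 0.121). PRR5 lost its call with the middle and highest run (adjusted p = 0.102 and 0.104). In the jasmonate list, 0 of the 8 tested members rose and 0 fell, 0 and 0 adjusted over the list alone; 1 passed an unadjusted p under 0.05, DESeq2 called 0 and voom 0 (camera adjusted p = 0.565). JAZ1 was at 0.77 ± 0.63 (adjusted p = 0.449) and AOS at -0.25 ± 0.42, and neither direction held with 1 replicate left out. JAZ1 was at -0.21 without opt3-2 replicate 3 and 1.70 without Columbia-0 replicate 3. Only the block called it (0.81, adjusted p = 0.0356, with adjusted p from 0.0356 to 0.818 over its alternatives). AOS was at 0.25 without Columbia-0 replicate 3 and -0.94 without opt3-2 replicate 3. In the flavonoid list, 0 of the 7 tested members rose and 0 fell, 0 and 0 adjusted over the list alone; 0 passed an unadjusted p under 0.05, DESeq2 called 0 and voom 0 (camera adjusted p = 0.565), with CHS at -0.31 ± 0.28 and FLS1 at -0.24 ± 0.30. Only 4 heat shock members were tested, too few for a set test: 0 of the 4 tested members rose and 0 fell, 0 and 1 adjusted over the list alone; 1 passed an unadjusted p under 0.05, DESeq2 called 0 and voom 0, with HSP101 at -0.20 ± 0.10 and HSFA2 at -0.47 ± 0.23.

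Marker lists of other tissues and cell types were compared in the root libraries too. For photosynthesis genes, which mark leaf tissue, 0 of the 21 tested members rose and 0 fell, 0 and 0 adjusted over the list alone; 1 passed an unadjusted p under 0.05, DESeq2 called 1 and voom 0 (camera adjusted p = 0.227), with LHCA4 at 0.33 ± 0.19 and LHCB1.3 at 0.32 ± 0.40 (-0.35 without opt3-2 replicate 1). The list was called higher without Columbia-0 replicate 3 or opt3-2 replicate 3 (adjusted p from 0.00607 to 0.0372), and LHCA4 was called without opt3-2 replicate 3 (adjusted p = 0.0382, and from 0.00993 to 0.656 over all its alternatives). The lowest value of LHCA4 came from voom on 36 libraries, which counts runs as samples. Of the root hair markers, 1 of the 7 tested members rose and 0 fell, 1 and 0 adjusted over the list alone (camera adjusted p = 0.807). The regulator RSL4 rose (1.42 ± 0.20), LRX1 was at -0.26 ± 0.23, and PRP3 was at -0.60 ± 0.24 (adjusted p = 0.111). PRP3 was called lower under the replicate block (-0.63, adjusted p = 0.0134), with limma voom (0.0130) and with the lowest run (0.0341). It was also called without opt3-2 replicate 3 (adjusted p = 0.0173) and with voom on 36 libraries (9.88e-07), which counts runs as samples. Over all its alternatives adjusted p ran from 9.88e-07 to 0.387. Of the endodermis markers, 0 of the 7 tested members rose and 0 fell, 0 and 0 adjusted over the list alone; 0 passed an unadjusted p under 0.05, DESeq2 called 0 and voom 0 (camera adjusted p = 0.538), with CASP1 at -0.22 ± 0.19 and CASP2 at -0.22 ± 0.18. Of the phloem markers, 1 of the 5 tested members rose and 0 fell, 2 and 1 adjusted over the list alone (camera adjusted p = 0.283). SUC2 rose (0.47 ± 0.08), and FTIP1 was at -0.21 ± 0.07 (adjusted p = 0.0660). FTIP1 was called lower with upper-quartile factors (adjusted p = 0.0385), limma voom (0.0356) and voom on 36 libraries (0.0224), with 0.0224 to 0.204 over its alternatives. The remaining 5 of the 8 largest decreases in roots were in genes of low abundance, at 3.40 CPM or less on average in Columbia-0 roots, and PGA4, AT3G07820 and VGD1 among them are known from pollen. PGA4 (-3.84 ± 0.88), AT5G19580 (-3.33 ± 0.75) and UNE15 (-3.29 ± 0.61) fell. AT3G07820 (-3.57 ± 0.97) lost its call without Columbia-0 replicate 2 or 3 or opt3-2 replicate 1 or 3 (adjusted p from 0.0596 to 0.0960), and VGD1 (-3.03 ± 0.90) without Columbia-0 replicate 2 or 3 or opt3-2 replicate 1 or 3 (adjusted p from 0.0759 to 0.125). With a fit per tissue PGA4, AT3G07820, AT5G19580 and VGD1 were not called (adjusted p from 0.0524 to 0.101), and single runs lost the call of UNE15 (0.132 with the lowest run and 0.0620 with the highest). Without opt3-2 replicate 1 the values of PGA4, AT3G07820, AT5G19580, UNE15 and VGD1 were -3.20, -2.93, -2.68, -2.69 and -2.40, and without opt3-2 replicate 2 they were -5.77, -5.07, -5.29, -4.16 and -4.41. Without Columbia-0 replicate 3, PGA4 and AT3G07820 were at -3.17 and -2.79.

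FER3, CSD2 and PR5 were among the genes that rose in opt3-2 leaves. FER3 (AT3G56090), a ferritin gene, rose from 29.6 ± 1.81 to 118 ± 4.14 CPM (2.00 ± 0.08, adjusted p = 1.30e-07). CSD2 (AT2G28190), the chloroplast copper/zinc superoxide dismutase, rose from 157 ± 4.66 to 518 ± 8.27 CPM (1.72 ± 0.05, adjusted p = 4.23e-08). PR5 (AT1G75040), a pathogenesis-related gene, rose from 146 ± 33.8 to 1275 ± 477 CPM (3.13 ± 0.28, adjusted p = 1.99e-05). Of 21692 genes tested, 6090 differed at an adjusted p under 0.05, 3349 higher and 2741 lower. With RLE factors 2874 were higher and 3268 lower, and with upper-quartile factors 2792 and 3028. Of the 6090, 779 were at least 2-fold higher and 544 at least 2-fold lower. The 8 largest increases began with AT5G22890 (6.21 ± 0.35) and AT3G49340 (1.92 ± 0.0818 to 60.8 ± 25.8 CPM, 4.98 ± 0.31). They also held AT4G28420 (4.63 ± 0.37), AT4G22960 (4.51 ± 0.30), SLAH4 (4.42 ± 0.56), PDF1.2 (4.37 ± 0.48) and CYP82C2 (4.35 ± 0.23). All 6 Columbia-0 leaf reads of SLAH4 were in replicate 3, and without it the fitted value, against 0 reads, was 8.92, which is no bound. Without the same replicate AT4G22960 was at 5.21 and PDF1.2 at 5.04. The 8th was CBL7, with 0 reads in Columbia-0 leaves and 9 in opt3-2 leaves (at least 2.15-fold higher, leaving out the counting error of the 9 reads). The call of CBL7 was lost with single runs and with voom on 36 libraries (adjusted p from 0.0140 to 0.554 over its alternatives).

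The 8 largest decreases in leaves included CYP94B1 and CYP94B3, enzymes of jasmonate catabolism. CYP94B1 (AT5G63450), which oxidizes jasmonoyl-isoleucine, fell from 2.87 ± 1.41 to 0.218 ± 0.0824 CPM (-3.67 ± 0.44, adjusted p = 1.40e-04), and AT1G33760 fell by 3.71 on the log2 scale. The related CYP94B3 (-4.32 ± 1.08) lost its call without Columbia-0 replicate 1 (adjusted p = 0.0514, and from 3.91e-04 to 0.0639 over all its alternatives). DDF1, a stress-responsive AP2 transcription factor gene (-5.06 ± 1.73), lost its call without any 1 of the 6 replicates (adjusted p from 0.0561 to 0.157). PELPK2 (-4.12 ± 0.77) and UMAMIT4 (-3.56 ± 0.84) fell from 0.250 and 0.279 CPM, and both lie above 10 CPM in roots. PELPK2 lost its call with the highest run (adjusted p = 0.343) and UMAMIT4 with the lowest and middle run (0.0972 and 0.173). Without opt3-2 replicate 1 their fitted values were -5.99 and -6.21. Without Columbia-0 replicate 1, DDF1, CYP94B3 and AT1G33760 were at -4.02, -3.19 and -2.85, and without opt3-2 replicate 3 at -6.15, -5.91 and -4.66. With no reads in opt3-2 leaves, AT5G13900 was at least 5.07-fold lower and AT1G60750 at least 1.82-fold lower. Both values leave out the counting error in Columbia-0 leaves, where reads of these genes were few, so they are no safe bounds. AT5G13900 lost its call with voom on 36 libraries and with the middle and highest run (adjusted p = 0.0837, 0.136 and 0.101). Its fitted value, which is no bound, was -5.33, and -4.54 without Columbia-0 replicate 2. AT1G60750 lost its call without Columbia-0 replicate 3 or opt3-2 replicate 1, 2 or 3 (adjusted p from 0.0781 to 0.0900). A separate list of 12 touch, wound and cold genes, chosen after these decreases were seen, had 1 member (JAZ7) past the test in leaves. The median log2 CPM of that list in each library, averaged over replicates, differed by -1.72 between opt3-2 and Columbia-0 leaves.

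In leaves, 1 of the 4 iron lists was called, that of iron storage and excess. In the iron storage and excess list, 7 of the 10 tested members rose and 0 fell, 7 and 0 adjusted over the list alone (median 0.99, camera adjusted p = 1.04e-04, but adjusted p = 0.0656 with an estimated correlation). NAS3, a nicotianamine synthase gene, rose from 27.4 ± 7.63 to 154 ± 6.74 CPM (2.49 ± 0.23), the metal-nicotianamine transporter gene YSL1 by 1.45 ± 0.10 and the ferritin gene FER4 by 1.14 ± 0.10. Of the root iron uptake list, 3 of the 20 tested members rose and 1 fell, 3 and 1 adjusted over the list alone (camera adjusted p = 0.791). FIT, the transcription factor of root iron uptake, stood at 4.37 CPM in opt3-2 leaves (1.06 ± 0.18), AT3G07720 rose (0.75 ± 0.16) and AHA2 rose (0.67 ± 0.13). ABCG37, a coumarin exporter (-0.84 ± 0.25), lost its call without Columbia-0 replicate 1 or 2 or opt3-2 replicate 1 or 2 (adjusted p from 0.0591 to 0.0692). Of the iron deficiency regulators, 5 of the 17 tested members rose and 1 fell, 5 and 1 adjusted over the list alone (camera adjusted p = 0.791). IMA1 (1.88 ± 0.44), IMA2 (1.80 ± 0.44), BTSL2 (0.80 ± 0.18) and FRO3 (0.79 ± 0.15) rose, and ORG1 (0.26 ± 0.08) too, named after its value was seen. The member that fell was ZIF1. In the iron trafficking list, 2 of the 13 tested members rose and 2 fell, 2 and 2 adjusted over the list alone (camera adjusted p = 0.990). YSL2 fell from 19.9 ± 6.71 to 3.54 ± 0.378 CPM (-2.48 ± 0.23). The calls of 3 smaller changes were close to the threshold: FPN1 (-0.44 ± 0.13) lost its call without Columbia-0 replicate 2 or opt3-2 replicate 3 (adjusted p from 0.0722 to 0.0766), NRAMP4 (0.38 ± 0.09) without Columbia-0 replicate 2 or 3 (adjusted p from 0.0507 to 0.0596), and NRAMP3 (0.34 ± 0.09) without any 1 of the 6 replicates (adjusted p from 0.0501 to 0.111).

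Several copper genes also changed in opt3-2 leaves. FSD1 fell from 923 ± 110.2 to 229 ± 6.32 CPM (-2.01 ± 0.26) and the copper transporter gene COPT2 from 8.16 ± 2.64 to 2.00 ± 0.0429 CPM (-2.02 ± 0.21). CITF1 (-2.58 ± 0.71) was near the detection limit, with 0.143 CPM in Columbia-0 leaves, and lost its call without Columbia-0 replicate 2 or opt3-2 replicate 2 or 3 (adjusted p from 0.0583 to 0.0821). Without opt3-2 replicate 1 its fitted value was -5.23. In the copper deficiency list, 0 of the 10 tested members rose and 6 fell, 0 and 6 adjusted over the list alone (median -1.16, camera adjusted p = 0.00581, but adjusted p = 0.103 with an estimated correlation). Of the copper proteins, 3 of the 10 tested members rose and 2 fell, 3 and 3 adjusted over the list alone (camera adjusted p = 0.209, but adjusted p = 2.99e-06 by fry, higher). CSD1 (1.39 ± 0.08), CSD2 and CCS (1.35 ± 0.06) rose, and PAA2 (-0.30 ± 0.09), a chloroplast copper pump, lost its call without opt3-2 replicate 3 (adjusted p = 0.0582, and from 4.11e-06 to 0.0582 over all its alternatives). The other member that fell was PAA1 (-0.26 ± 0.08), named after its value was seen. In the zinc deficiency list, 1 of the 8 tested members rose and 1 fell, 1 and 1 adjusted over the list alone (camera adjusted p = 0.857). ZIP5 rose (1.16 ± 0.14), and ZIP1 (-0.38 ± 0.11) lost its call without Columbia-0 replicate 1 or opt3-2 replicate 3 (adjusted p from 0.0562 to 0.0631). In the sulfate list, 2 of the 9 tested members rose and 0 fell, 2 and 0 adjusted over the list alone (camera adjusted p = 0.257), with LSU1 (2.07 ± 0.31) and SULTR1;2 (1.18 ± 0.12) higher. The list was called higher without Columbia-0 replicate 2 (adjusted p = 0.0488, and from 0.0488 to 0.915 over all its alternatives). In the metal chelation list, 3 of the 9 tested members rose and 2 fell, 3 and 2 adjusted over the list alone (camera adjusted p = 0.990). MT2A (0.60 ± 0.13) and the vacuolar phytochelatin transporter gene ABCC1 (0.51 ± 0.08) rose and GSH1 fell (-0.40 ± 0.07), as did GSH2 (-0.22 ± 0.05), named after its value was seen, while ABCC2 (0.46 ± 0.12) lost its call without Columbia-0 replicate 2 or 3 or opt3-2 replicate 1 or 2 (adjusted p from 0.0516 to 0.0671).

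Defence and oxidative stress genes rose in opt3-2 leaves. Of the oxidative stress list, 8 of the 15 tested members rose and 0 fell, 8 and 0 adjusted over the list alone (median 0.95, camera adjusted p = 9.02e-05, but adjusted p = 0.169 with an estimated correlation). GSTU25 (3.85 ± 0.34), GSTF6 (1.96 ± 0.22), GSTF7 (1.85 ± 0.17) and GSTU24 (1.66 ± 0.21) rose, and GSTU25 was at 4.53 without Columbia-0 replicate 3. In the salicylate defence list, 7 of the 10 tested members rose and 0 fell, 7 and 0 adjusted over the list alone (median 0.76, camera adjusted p = 9.35e-04, but adjusted p = 0.305 with an estimated correlation). PR2 rose from 224 ± 56.5 to 1473 ± 515 CPM (2.72 ± 0.26) and PR1 from 62.1 ± 27.4 to 289.9 ± 47.3 CPM (2.22 ± 0.25). FMO1 (1.39 ± 0.39) lost its call without Columbia-0 replicate 1 or 2 or opt3-2 replicate 3 (adjusted p from 0.0769 to 0.0877), and its value was 2.17 without Columbia-0 replicate 3. In the jasmonate list, 1 of the 8 tested members rose and 1 fell, 1 and 1 adjusted over the list alone (camera adjusted p = 0.791). The defensin gene PDF1.2 rose from 3.11 ± 2.03 to 66.1 ± 31.7 CPM, and JAZ10 (-2.01 ± 0.65) lost its call without Columbia-0 replicate 1 or 3 or opt3-2 replicate 1, 2 or 3 (adjusted p from 0.0755 to 0.118). In the flavonoid list, 0 of the 7 tested members rose and 0 fell, 0 and 0 adjusted over the list alone; 0 passed an unadjusted p under 0.05, DESeq2 called 0 and voom 0 (camera adjusted p = 0.791), with CHS at -0.04 ± 0.27 and DFR at 0.05 ± 0.25.

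Of the circadian clock genes in leaves, 5 of the 10 tested members rose and 2 fell, 5 and 2 adjusted over the list alone (camera adjusted p = 0.624). PRR5 rose (1.05 ± 0.17), and so did PRR7 (0.31 ± 0.09) and PRR9 (0.49 ± 0.08), while LHY fell (-0.44 ± 0.09). These last 3 were named after their values were seen. PRR5 lost its call with the middle run (adjusted p = 0.261). GI (0.73 ± 0.17) lost its call without Columbia-0 replicate 2 (adjusted p = 0.0529, and from 3.22e-04 to 0.0529 over all its alternatives), TOC1 (0.51 ± 0.15) without Columbia-0 replicate 1 or 2 or opt3-2 replicate 1, 2 or 3 (adjusted p from 0.0534 to 0.121), and ELF4 (-1.27 ± 0.42) without Columbia-0 replicate 1 or 3 or opt3-2 replicate 1 or 2 (adjusted p from 0.0570 to 0.187). Of the photosynthesis genes, 0 of the 21 tested members rose and 1 fell, 0 and 0 adjusted over the list alone (median -0.24, camera adjusted p = 0.102). The list was called lower with a fit per tissue (adjusted p = 1.19e-04) and with the replicate block (0.0421), with adjusted p from 1.19e-04 to 0.915 over its alternatives. LHCB1.2 (-0.44 ± 0.14), which shares sequence with LHCB1.3, lost its call without Columbia-0 replicate 1 or 2 or opt3-2 replicate 1, 2 or 3 (adjusted p from 0.0632 to 0.0885), and LHCB1.3 (-0.39 ± 0.39) and RCA (-0.24 ± 0.15) did not pass. The fit per tissue called both (adjusted p = 8.57e-04 and 0.0281). So did voom on 36 libraries, which counts runs as samples and gave the lowest adjusted p of both. Over their alternatives adjusted p ran from 6.53e-05 to 0.591 for LHCB1.3 and from 6.26e-08 to 0.402 for RCA. Of the phloem markers, 0 of the 5 tested members rose and 3 fell, 0 and 3 adjusted over the list alone (median -0.28, camera adjusted p = 0.0219, but adjusted p = 0.305 with an estimated correlation). SUC2 fell from 337 ± 19.8 to 213 ± 12.9 CPM (-0.66 ± 0.08) and FTIP1 by 0.45 on the log2 scale; AHA3 (-0.28 ± 0.08) lost its call without Columbia-0 replicate 2 or opt3-2 replicate 1 (adjusted p from 0.0558 to 0.0561). Root hair and endodermis markers stand for root tissue in leaf libraries. In each of these 2 lists edgeR called 0 of the 7 tested members, with 0 adjusted over the list alone and 0 past an unadjusted p under 0.05, and DESeq2 and voom called 0 (camera adjusted p = 0.795 and 0.857). PRP3 was at 0.33 ± 0.58 (-0.65 without opt3-2 replicate 3), COBL9 at -0.06 ± 0.70, ESB1 at 0.69 ± 0.52 and CASP2 at -1.09 ± 0.63. With 1 replicate left out ESB1 ran from 0.22 to 1.60. Of the heat shock genes, 0 of the 4 tested members rose and 0 fell, 0 and 0 adjusted over the list alone; 1 passed an unadjusted p under 0.05, DESeq2 called 0 and voom 0, with HSP101 at -0.10 ± 0.11 and HSP18.2 at -0.40 ± 0.17.

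**Figure D3:**
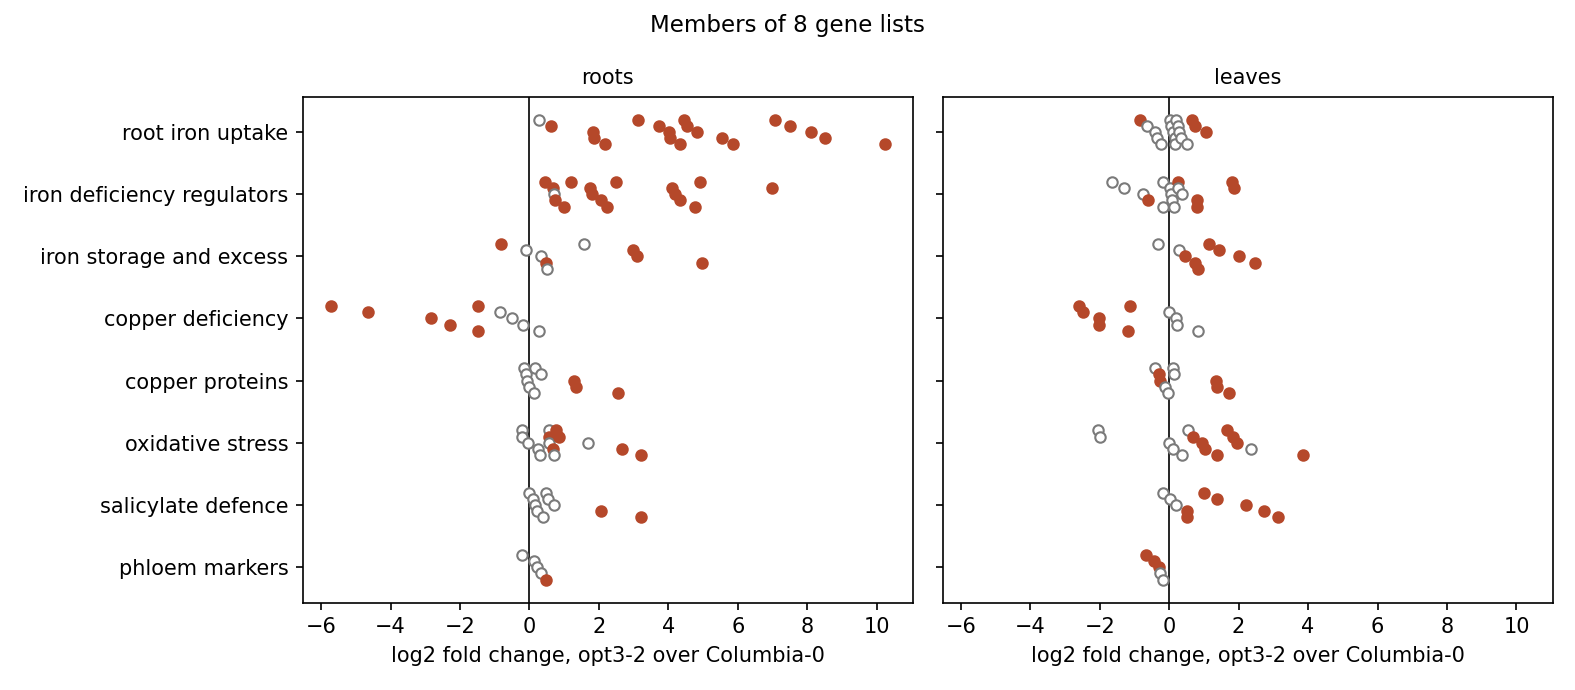
Log2 fold changes of opt3-2 over Columbia-0 for the tested members of 8 gene lists, in roots (left) and leaves (right); each point is 1 gene, filled where its adjusted p is under 0.05, and vertical offsets within a list only separate points. Left out are 4 points of genes with 0 reads in 1 genotype of that tissue. Root iron uptake genes have a median of 4.38 in roots and 0.14 in leaves.

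The effect of opt3-2 differed between the tissues for many of these genes. In the test of the leaf effect minus the root effect, 3503 genes passed, 1834 with a positive and 1669 with a negative difference. Of the root iron uptake list, 16 of 20 members had a more negative effect in leaves and 0 a more positive one (median difference -4.35, camera adjusted p = 3.39e-23, but adjusted p = 0.0839 with an estimated correlation). Of the iron deficiency regulators, 14 of 17 did (median -1.38, camera adjusted p = 1.02e-10, but adjusted p = 0.0974 with an estimated correlation). Some uptake genes, such as CYP82C4, S8H and NAS2, were at 1.06 CPM or less in every leaf replicate, so their difference is mainly the root change. The sulfate (0.53, adjusted p = 0.0427), photosynthesis (-0.39, adjusted p = 0.0325) and phloem lists (-0.50, adjusted p = 0.0183) also passed with the preset correlation. With an estimated correlation their adjusted p was 0.649, 0.696 and 0.359. Fry did not call the photosynthesis list here (adjusted p = 0.376), and of the lists that camera did not call it called iron storage and excess (1.31e-05), iron trafficking (3.41e-04) and zinc deficiency (0.0403) lower and copper deficiency (3.41e-04) higher. For iron storage and iron trafficking the median difference was 0.30 and 0.02, against a mean of -1.30 and -0.62. Genes called in opposite directions included GRF11, a 14-3-3 protein gene (3.47 in roots, -0.48 in leaves, interaction adjusted p = 1.34e-07), and CAT5, an amino acid transporter gene (-1.73 and 2.16). AT3G54880 (1.38 and -0.61) and ROPGAP3 (1.28 and -0.72) rose in roots and fell in leaves. AT5G59530 (-0.44 and 3.17) and CHX16 (-0.93 and 2.29) did the reverse. Among list members, ABCG37 (3.13 and -0.84), ZIF1 (0.68 and -0.62) and SUC2 (0.47 and -0.66) were higher in roots and lower in leaves. YSL3 (-0.83 and 0.46) and SULTR1;2 (-0.86 and 1.18) were lower in roots and higher in leaves. ELF4 (0.76 and -1.27) also had opposite signs, and its interaction call was lost without Columbia-0 replicate 3 (adjusted p = 0.0540, and from 0.00283 to 0.294 over all its alternatives).

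Genes called in both tissues numbered 1274, and 937 of them (73.5%) changed in the same direction. Of these, 571 rose in both tissues, against 277 for independent lists of the same sizes, and 366 fell in both, against 200. In opposite directions there were 337, 168 higher in roots and lower in leaves (227 for independent lists) and 169 lower in roots and higher in leaves (244). One-sided Fisher exact tests gave adjusted p = 1.08e-73 and 3.72e-33 for the 2 same-direction pairs, over genes, which are not independent replicates. List members called the same way in both tissues included the copper genes FSD1, YSL2, CITF1, CCH, CSD1, CSD2 and CCS and the iron genes FIT, AT3G07720, IMA1, IMA2, BTSL2, FRO3, ORG1, FER3, VTL1, VTL2, FPN1, NRAMP3 and NRAMP4. The others were the oxidative stress genes GSTU25, GSTU24, GSTF6, APX1, CAT1 and AOX1A, the clock genes PRR5 and PRR9, and MT2A. CCH, CAT1 and AOX1A were named here after their values were seen. Not all of these calls were stable. CITF1, FPN1, NRAMP3 and NRAMP4 in leaves and GSTF6 in roots lost theirs without certain single replicates. IMA1 and IMA2 in leaves and PRR5 in both tissues lost theirs with certain single runs. The root and leaf comparisons share no libraries but share the fitted spread. Across all tested genes the 2 sets of log2 fold changes correlated at r = 0.113. The same-direction count was 587 without Columbia-0 root replicate 2. The opposite-direction count was 568 without opt3-2 root replicate 3 and 216 to 218 without Columbia-0 root replicate 1 or opt3-2 leaf replicate 1 or 2.

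Some marker genes of leaf and of root differed strongly between Columbia-0 leaf and root libraries. The genes shown were picked as the called list members with the largest changes in this comparison. They are not typical members and are only a weak check of the tissue labels. RBCS2B (AT5G38420), a small subunit of Rubisco, was at 2.29 CPM in roots and 2120.4 CPM in leaves (9.86 ± 0.27), and LHCB1.2, a light-harvesting protein gene, differed by 9.70 ± 0.20. The root hair genes EXPA7 and RSL4 had 0 reads in Columbia-0 leaves and were at least 546-fold and at least 92.3-fold lower there. Of the genes tested, 16798 differed between the tissues, 7860 higher in leaves and 8938 higher in roots. The median of all genes was -0.06 on the log2 scale with TMM factors and -0.25 with upper-quartile factors, and tissue differences are to be read relative to that shift.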

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

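The tests on FER1 and MT2B, on pollen genes and on handling were chosen only after the results were seen. The test on MT1A and F3H and the regrouping of samples were set beforehand.

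The effect of opt3-2 differed between leaves and roots for 3503 genes, by a test of the difference itself. Of the 200 arrangements of the samples, 100 were drawn, and 2 of these splits gave as many, the real one included. The other, which swaps the genotypes in leaves alone and so tests the sum of the 2 effects, gave 6028. Over all 200, the count was 0 in the 162 where neither tissue had its real split, 1004 to 2864 where only leaves had it and 316 to 491 where only roots had it. Regrouping thus also removes the genotype effect of a tissue, so this count cannot tell whether chance gave a difference between tissues, and the test of the difference stands alone. Among lists, the median difference was -4.35 for root iron uptake, -1.38 for iron deficiency regulators, 0.53 for sulfate assimilation, -0.39 for photosynthesis and -0.50 for phloem markers. For each gene below, the leaf effect minus the root effect, as log2 fold change, passed that test.

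The mutated gene gave OPT3 -1.99. Among iron genes the difference was CYP82C4 -10.66, S8H -9.15, NAS2 -7.86, CYP71B5 -7.30, FIT -0.76, ABCG37 -3.96, AT3G07720 -4.08, BHLH100 -8.65, BHLH38 -5.61, IMA2 -3.11, BTSL2 -1.01, FRO3 -1.28 and ZIF1 -1.31. For iron storage and transport it was VTL5 -5.30, VTL1 -2.25, VTL2 -2.26, FRD3 -5.16, FPN3 -1.72, NRAMP3 -1.26, FER3 1.51, FER4 0.80, YSL1 1.54 and YSL3 1.3. For copper, zinc and chelation genes it was YSL2 -0.99, FRO5 4.86, ZIP2 3.67, COPT2 -2.28, CSD1 -1.17, CSD2 0.43, ZIP9 -3.12, ZIP5 1.36, ZIP1 -0.59, HMA2 0.76, GSH1 -0.41 and ABCC1 0.56. CYP82C4, S8H, NAS2, BHLH100, FRD3 and FRO5 were at 1.70 CPM or less in every leaf replicate, so their differences mainly restate the root change. Sulfate, stress and defence genes gave SULTR1;2 2.04, GSTU24 -1.01, GSTF6 1.12, GSTF7 2.05, APX1 0.63, ALD1 -3.20, WRKY70 -2.23, PR5 2.60, PR2 2.32, PDF1.2 3.45 and JAZ10 -3.54. Clock and phloem genes gave ELF4 -2.03, SUC2 -1.13 and AHA3 -0.50. Genes named for large root changes gave AT1G73120 -6.29, AT5G55620 -8.49, AT1G52120 -7.29, AT5G19580 2.90 and UNE15 2.97. Those named for large leaf changes gave AT5G22890 4.03, AT4G22960 4.50, SLAH4 5.85, DDF1 -7.21, CYP94B3 -5.91, CYP94B1 -3.22, PELPK2 -3.96, AT1G33760 -6.31 and UMAMIT4 -3.15. CBL7, AT5G13900 and AT1G60750 had 0 reads in a leaf group, and their fitted values, which are no bounds, were CBL7 5.21, AT5G13900 -4.94 and AT1G60750 -6.97. Genes called in opposite directions gave GRF11 -3.95, CAT5 3.89, AT3G54880 -2.0, AT5G59530 3.62, CHX16 3.22 and ROPGAP3 -2.01.

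Some list genes known as expressed were at or near 0 reads: MT1A (chromosome 1, 2338904 to 2339321) and MT2B (chromosome 5, 506498 to 507244) at 0, FER1 (chromosome 5, 227953 to 230051) at 2 and F3H (chromosome 3, 19025192 to 19026872) at 14 over all 12 replicates. A candidate explanation is that reads in overlapping gene models were not counted: 54.8% of 332 protein-coding genes wholly inside another gene had fewer than 10 reads, against 16.6% of 20193 that meet no other gene and 4.92% of 6185 partly inside one. MT1A lies wholly inside AT1G07590 (342642 reads), but 93.8% of F3H exon bases do so in a gene with 0 reads (AT3G51238), so for this pair the explanation stays open. It is argued against for MT2B, with 0% of exon bases inside another gene in TAIR10.1, and FER1, with 46.2%, although the annotation used for counting is not known. No biological explanation was tested, since the design gives none for a gene without reads in every group.

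Some pollen-type genes were lower in opt3-2 roots. Of 14 genes of a separate pollen list, 11 were tested and 10 were under 2 CPM in every root library. In roots edgeR called 4 of the 11 lower and 7 did not pass (7 at an unadjusted p under 0.05, 5 called by DESeq2 and 2 by voom). In leaves edgeR called 0 (1 at an unadjusted p under 0.05, 0 by DESeq2 and by voom). The median log2 fold change of the 10 under 2 CPM was -2.50 in roots and -0.48 in leaves, and no set test was run on them. A candidate explanation is pollen or flower tissue carried over, and the median correlation between pairs of those under 2 CPM was 0.532 within groups, against 0.244 over all 11. The summed level of the 10 under 2 CPM was 4.63, 6.75 and 9.33 CPM in Columbia-0 roots, 3.20, 4.30 and 3.77 CPM in opt3-2 roots and 3.43 to 9.94 CPM in leaves, while STP9 (-0.10), ACT4 (-0.39) and PRF4 (0.22) did not pass in roots and TUA1, the most abundant member, is expressed in both tissues (21.6 CPM in Columbia-0 roots). A genotype effect on these genes was not tested apart from this and stays open.

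DDF1, CYP94B1 and CYP94B3 were lower in opt3-2 leaves. A candidate explanation is handling or harvest: in a separate list of 12 touch, wound and cold genes, replicates of 1 group differed by up to 3.70 log2 CPM, in Columbia-0 roots, and by up to 2.99 in opt3-2 roots, on the median of the list in each library. The group means of that median differed by -1.72 between genotypes in leaves. In leaves, replicates of 1 group differed by at most 0.961 and 0.909, less than the genotypes did, so genotype stays open as well. In roots, replicates of equal number moved together (2.75, 5.20 and 6.45 in Columbia-0, 3.89, 4.95 and 6.88 in opt3-2). In leaves 1 of the 12 was called lower by edgeR (JAZ7; 4 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by voom), and in roots 0 (1 at an unadjusted p under 0.05, 0 by DESeq2 and by voom).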

How the results depend on the processing

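Of the alternatives given in this part, the fit with the run set of Columbia-0 as a covariate was chosen after the results were seen. That fit parts run sets within Columbia-0 only and does not correct the genotype comparison for run set. Run numbers could not be matched to technical replicate numbers, so the single-run alternatives took the lowest, middle or highest run of each replicate.

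The 3377 genes called in roots became 5233 with voom on 36 libraries, 2243 with the highest run, 1973 with a fit per tissue, 821 with a 2-fold minimum and 1572 at an adjusted p under 0.01; leaving out 1 replicate gave 2074 to 4231. The 6090 in leaves became 7707 with a fit per tissue, 1323 with the 2-fold minimum and 3446 at 0.01 (4138 to 5342 without 1 replicate). The 3503 that differed between tissues became 2315, 2223 and 2278 with the lowest, middle and highest run, 1319 with the 2-fold minimum and 1590 at 0.01 (2503 to 4540 without 1 replicate). The 16798 between tissues became 9634 with the 2-fold minimum. The 937 shared in direction became 1513 with voom on 36 libraries, 574, 524 and 543 with single runs, 125 with the 2-fold minimum and 338 at 0.01 (587 to 1139 without 1 replicate). Single runs hold fewer reads, and stricter thresholds call fewer genes by construction. Voom on 36 libraries counts runs as samples, which can raise its counts. For it and for the fit per tissue the cause was not tested. With an estimated correlation, camera called 4 lists in roots and 0 in leaves, where 3 had an unadjusted p under 0.05 and fry called 6. The run-set covariate gave 2926 genes in roots, 5651 in leaves, 2892 for the difference and 846 shared, and it was the only alternative that called OPT3 in roots (-0.47, adjusted p = 0.0494, with 0.0494 to 0.476 over all); the cause was not tested. OPT3 in leaves stayed between -2.58 and -2.24. No scaling moved the share of higher calls by over 10 percentage points: in roots 53.2% became 46.2% with upper-quartile factors, in leaves 55.0% became 46.8% with RLE, for the difference 52.4% became 43.0% with RLE, and between tissues 46.8% became 38.4% with upper-quartile factors.

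Of 2997 comparisons over 156 results of named genes, 2790 kept direction and side of the threshold, 165 fell short, 17 newly passed and 25 changed sign, and 103 results never changed. Leaving out 1 replicate accounted for 83 of the lost calls. Single runs, with less depth, accounted for 16, 17 and 18. For lists, 417 of 465 comparisons over 36 results kept direction and call, 11 lost the call, 16 gained it and 21 changed direction, and 10 never changed.

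The 25 changes of sign were in 8 results of genes and the 21 in 10 lists, and 0 of them passed the test before or after; the cause was not tested. As log2 fold changes without 1 replicate, GSH1 in roots ran from -0.039 to 0.054, LHCB1.3 from -0.35 to 0.73, JAZ1 from -0.21 to 1.70 and AOS from -0.94 to 0.25. In leaves CHS ran from -0.25 to 0.28, DFR from -0.22 to 0.44, PRP3 from -0.65 to 0.64 and COBL9 from -0.69 to 0.28. GSH1 was at -0.017 with upper-quartile factors and -0.0038 with a fit per tissue. CHS was at 0.025 with voom, 0.0041 with voom on 36 libraries, 0.018 with the replicate block and 0.0059 with the run-set covariate. DFR was at -0.019 with the lowest run, and COBL9 at 0.75 with the lowest and 0.16 with the middle run. For lists, adjusted p carries a minus sign where the list leaned lower. Without 1 replicate it ran in roots from -0.953 to 0.0827 for photosynthesis, -0.790 to 0.953 for root hair and -0.953 to 0.932 for endodermis markers. In leaves it ran from -0.896 to 0.877 for iron deficiency regulators, -0.987 to 0.979 for iron trafficking, -0.925 to 0.979 for metal chelation, -0.896 to 0.979 for jasmonate, -0.925 to 0.512 for flavonoids, -0.925 to 0.925 for root hair and -0.925 to 0.979 for endodermis markers. Fry gave 0.977 for root hair markers in roots. Iron trafficking in leaves was at 0.900 with a fit per tissue, 0.982 with the replicate block and 0.948 with the run-set covariate.

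With a fit per tissue, PGA4, AT3G07820, AT5G19580, VGD1, ZIP3, APR2, GSTF6, WRKY70 and ELF4 lost their calls in roots (adjusted p from 0.0524 to 0.107). The clock list in roots (adjusted p = 0.0405) and, in leaves, the photosynthesis list, LHCB1.3 and RCA gained theirs.

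With the replicate block, 3563 genes were called in roots, 6367 in leaves, 3760 for the difference, 15119 between tissues and 1034 shared, with 9 lists in roots and 6 in leaves. Of these genes, 2940 in roots, 5579 in leaves and 3098 for the difference were also called by the main fit. In roots opt3-2 replicate 2 correlated better with Columbia-0 replicate 1 (r = 0.182) than with its own number (0.157). In leaves the numbers do not pair the samples (r = -0.0722, -0.0393 and 0.00685), and not every sample correlates best with its own number. There the block gave adjusted p = 0.0639 for ABCG37, 0.0547 for CITF1, 0.0512 for ZIP1 and 0.0630 for ELF4, and 0.0421 for the photosynthesis list. Apart from these and from JAZ1, PRP3 and the sulfate and clock lists in roots, the block changed no other call of a named gene or list.

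The splits of 6 samples number 10 with the real one, too few for a share under 0.05. Every other split also has both genotypes, or both tissues, on each side. A real effect then widens the spread within the sides, so low gene counts there cannot tell whether chance gave the real count. The sides hold the genotypes in unequal numbers, so part of a real effect also stays between them. The list counts of other splits thus do not show chance alone. In roots 1 of 10 splits, the real one, gave 3377 genes or more, and the highest other gave 3. With root numbers taken as pairs, the 3 other splits that part all 3 pairs gave 0 by edgeR (up to 1696 at an unadjusted p under 0.05), while the 6 that part 1 pair gave up to 3. In leaves 1 of 10 reached 6090, with 0 in the highest other (762 unadjusted), and between tissues 1 of 10 reached 16798, with 0 (317 unadjusted). For lists, 3 of 10 root splits reached 7, with 8 in the highest other, and 1 of 10 leaf splits reached 5, with 4. For genes shared in direction, 1 of 100 splits reached 937. The highest other gave 337, and it swaps the leaf genotypes, so it counts the genes called in opposite directions. The rest gave 0 by edgeR, since 1 or both tissues then had few calls, so this count does not test sharing beyond the calls themselves. The opposite-direction count of 337 ran from 26 to 648 over its alternatives and from 216 to 568 without 1 replicate. Depth limits genes near 0 reads. Folds are given as bounds only where a group had 0 reads, and other genes with few reads have fitted values.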

Other observations

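The tests on the gene groups of the first paragraphs were chosen only after the main results were seen, as a family of 8 tests; the test on genes near OPT3 was set beforehand.

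Of 12 class III glutaredoxin genes, small redox proteins of which some are known from nitrate signalling, 7 rose in opt3-2 roots and 0 fell (median log2 fold change 2.59, camera adjusted p = 3.40e-05, and adjusted p = 0.0448 with an estimated correlation). Of the 7, 5 (GRXS3, GRXS4, GRXS5, GRXS7 and GRXS8) are similar neighbours on chromosome 4, from 8925571 to 8938124 in TAIR10.1, within 1 Mb of OPT3, and they may share reads. Without these 5, the set test did not pass (2 of 7 rose, median 1.32, camera adjusted p = 0.0751, and adjusted p = 0.390 with an estimated correlation). The 2 were GRXS9 on chromosome 2 and GRXS10 (2.90 ± 0.58) on chromosome 3. The called members were of low abundance: GRXS8 rose from 0.174 to 0.934 CPM (2.38 ± 0.40) and GRXS9 from 0.284 to 1.60 CPM (2.51 ± 0.49). The others rested on fewer reads in opt3-2 roots over the group, from 18 for GRXS3 (0 in Columbia-0) to 54 for GRXS10 (7 in Columbia-0). In leaves 3 rose and 1 fell (median -0.08, adjusted p = 0.771). Of 9 nitrate response genes, 0 rose and 5 fell in roots (median -0.66, camera adjusted p = 0.0114, but adjusted p = 0.210 with an estimated correlation). The nitrate transporter genes NRT1.1 (724 ± 85.0 to 300.4 ± 40.6 CPM, -1.27 ± 0.13) and NRT2.1 (1482 ± 157 to 777 ± 64.0 CPM, -0.93 ± 0.20) and the nitrate reductase gene NIA1 (-0.68 ± 0.12) fell there. In leaves 2 rose and 1 fell (median 0.14, adjusted p = 0.638), with NIA1 higher (1.06 ± 0.12).

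Indole and camalexin genes, of a defence compound made from tryptophan, rose and fell in opt3-2 leaves. Of 8 tested, 5 rose and 2 fell (median 2.01), and the set test did not pass (camera adjusted p = 0.0929, and 0.259 with an estimated correlation). CYP71A12 rose from 3.19 to 63.9 CPM (4.30 ± 0.39), and FOX1 (2.72 ± 0.19), MYB122 (2.54 ± 0.35), CYP71A13 (2.37 ± 0.34) and PAD3 (1.64 ± 0.35) rose. CYP79B3 (-1.35 ± 0.16) and CYP79B2 (-0.71 ± 0.20), which make indole-3-acetaldoxime, fell. In roots 2 rose and 0 fell (median -0.04, adjusted p = 0.638). Of 12 phosphate starvation genes, 9 were tested. In roots 0 rose and 3 fell (median -0.44, camera adjusted p = 0.0114, but adjusted p = 0.210 with an estimated correlation), and in leaves 4 rose and 3 fell (median 0.00, adjusted p = 0.638). There PHT1;4 (1.71 ± 0.23) and PLDZ2 (1.57 ± 0.18) rose and MGD3 (-1.87 ± 0.41) fell.

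The opt3-2 line may carry sequence differences linked to the insertion, which could change genes near OPT3 in both tissues. Within 1 Mb of OPT3, 21 of 419 tested genes (5.01%) were called the same way in both tissues, against 915 of 21126 elsewhere (4.33%). The ratio was 1.16 (one-sided Fisher exact p = 0.281), under the 1.5 times set as the bound, so no clear excess was seen near OPT3. With 21 genes the ratio is imprecise, so it does not exclude linked differences. Single neighbours are not excluded by a share. The largest changes among the 21 were in the glutaredoxin genes GRXS3 (18 reads in opt3-2 roots and 0 in Columbia-0 roots, and 0.91 in leaves) and GRXS4 (2.82 in roots and 1.67 in leaves), in ATARD2 (2.24 and 0.24), WRKY28 (1.59 and 0.96) and AT4G16260 (1.32 and 1.65). For the glutaredoxin neighbours linked differences stay open. The nearest of the 21, SPK1 and AT4G16330, were at -0.44 and 0.60 in roots and -0.32 and 0.47 in leaves.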
